A study of Homo sapiens with 9 samples.

How the data were processed

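Differentiated Caco-2 cells were sampled after 24 h in medium alone, with 10 µM carmine or with 20 µM carminic acid, and total RNA of 3 samples per group was sequenced, per the labels' protocols. The deposited values are raw counts per gene, 1 file per library, with NCBI Gene IDs as gene names. The reads were aligned with HISAT2, per the file headers. FastQC, HISAT, featureCounts and the build hg38 are named without versions, per the submitters' processing notes. The strand setting, the annotation release, the treatment of reads that map to several places and the library kit are not given in the sources used here, so counts of genes with close copies elsewhere carry an unknown share of such reads.

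Every file held 28395 genes, of which 27745 had a symbol in the reference table of GRCh38.p14 and 650 had none. Genes without a symbol took 0.0432% of all counts. Total counts ran from 54871018 to 57581301 per library. The share of counts on the mitochondrial chromosome was given per library with a 95% Wilson interval, which covers counting error only and was at most 0.00821 percentage points wide. Every pair of libraries of a group was compared by a chi-square test over genes with at least 20 counts in the pair. The chi-square per degree of freedom was 9.51 or more, so no library was counted as a copy of another.

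Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr by group, which left 16017 genes, and libraries were scaled by TMM factors. All 9 libraries were fitted in 1 quasi-likelihood model with robust estimation and no covariate, and 3 contrasts were tested two-sided: carmine against control, carminic acid against control, and carmine against carminic acid. P-values were adjusted by Benjamini and Hochberg over all tested genes of a contrast, with a threshold of 0.05. Standard errors were taken from the fold change and the F statistic, and intervals are 95% intervals from the same fit. The biological coefficient of variation was 10.9%. Levels are TMM-scaled CPM, as mean ± SD with n = 3.

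The groups, comparisons, lists, rule for named genes and most alternatives were fixed before the data were examined. The rule took the genes with the largest rise and fall past the threshold, with an average log2 CPM of at least 0 and no overlap of the groups. In a direction with no such gene, the 3 genes with the smallest p were taken as values. It also took the member with the smallest p of each list, and a fixed set of genes for metal, oxidant, xenobiotic, brush border and stress responses that is given whatever the test. HSPA1A belonged to that set and had too few counts to be tested, 18 in all libraries together.

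The 37 lists covered intestinal functions (enterocyte brush border and digestion, nutrient transporters, lipid transport and lipoproteins, tight and adherens junctions), metals (metallothioneins and zinc response, iron handling), defence (NRF2 antioxidant response, aryl hydrocarbon receptor response, xenobiotic metabolism and efflux, bile acid and FXR response, NF-kB and inflammatory cytokines, interferon response), stress and growth (unfolded protein response, ATF4 and amino acid response, heat shock, p53 and DNA damage, cell cycle and proliferation, apoptosis, immediate early genes, WNT targets and intestinal stem cells, epithelial-mesenchymal and extracellular matrix genes), metabolism (cholesterol biosynthesis, fatty acid synthesis, PPAR targets and fatty acid oxidation, hypoxia, glycolysis and gluconeogenesis, nuclear oxidative phosphorylation, mitochondrially encoded genes), cell machinery (cytosolic ribosomal proteins, replication-dependent histones, endocytosis, lysosome and autophagy) and other cell types (goblet and secretory, enteroendocrine and Paneth, hepatocyte-type, stromal, endothelial and immune, kidney and lung epithelium). All 818 list entries matched a gene in the files, and 711 different genes of the lists were tested. Lists with at least 5 tested members, 36 of the 37, were tested with camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of a contrast. Camera with an estimated correlation and fry, both from limma 3.58.1, were run beside it. For each list, members were also counted with p-values adjusted over the list alone.

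Alternatives changed 1 named choice each, or the pair named, with the gene filter applied again to the libraries kept and with DESeq2 and limma-voom used with their own steps: size factors of DESeq2 (RLE), library size alone, no filter beyond 1 count, CPM above 1 in 3 libraries, DESeq2 1.42.0, limma-voom with quality weights, non-robust estimation, the replicate letter as a block (also with library size alone), only the 6 libraries compared, an adjusted p under 0.01, an absolute log2 fold change of at least 1, and leaving out each library. The letters were not used to pair samples in the model reported, since libraries of the same letter did not deviate together: the correlations of their deviations from the group means lay between -0.149 and 0.0952 over 9 pairs. After the data had been seen, 3 analyses were added, besides the tests of explanations in the closing sections. The trends of each library with GC content and transcript length, fitted as splines with 5 degrees of freedom over genes with log2 CPM above 2, were removed as offsets. GC content and length were known for 96.5% of tested genes. Both colorants were pooled against control, and overlap of the responses was also counted at an unadjusted p under 0.05.

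The model was tested on simulated counts with the means, library sizes and spread of the real libraries, with 200 changed genes in each of 4 simulations on 16017 genes. For carmine against control, 12.5% of genes changed 1.25-fold, 55.5% of those changed 1.5-fold, 80.0% of those changed 2-fold and 97.5% of those changed 4-fold were recovered. For carminic acid against control the shares were 15.0%, 59.5%, 80.5% and 92.5%, and for carmine against carminic acid 14.5%, 56.0%, 78.5% and 94.5%. These simulations drew genes independently and held no trends of single libraries. Recovery also depends on the number of changed genes, so these shares need not hold for the real comparisons. The correlation and overlap of the 2 responses were compared with 40 simulations of unchanged groups that share the control libraries. Coordinates are those of GRCh38.p14.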

Results

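Differentiated Caco-2 cells, a human colon carcinoma line that forms an enterocyte-like layer in culture, were compared after 24 h in medium alone (control), with 10 µM carmine or with 20 µM carminic acid. Carminic acid is the red anthraquinone dye of cochineal insects, and carmine is its aluminium complex, so the compounds differ in the metal and, in this series, also in stated concentration. RNA-seq gave 3 libraries per group, with 54871018 to 57581301 counts per library and 16017 genes with enough counts for testing. The labels do not state that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Correlations of log2 CPM between libraries of a group lay between 0.988 and 0.994. Between libraries of different groups they lay between 0.988 and 0.993, so this measure did not set the groups apart. The first principal component, with 20.9% of the variance, set carmine library C (34.4) apart from the other libraries, which lay between -19.4 and 14.5.

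The carmine comparison asked which transcripts differed after exposure to the aluminium complex at 10 µM. Transcripts of the mitochondrial genome, which encode subunits of the respiratory chain and the mitochondrial rRNAs, fell as a list with carmine: all 15 tested genes had negative log2 fold changes, with a median of -0.92 (camera adjusted p = 5.69e-31; adjusted p = 0.268 with an estimated correlation). Their chromosome took 1.19% ± 0.185 of counts with carmine and 2.30% ± 0.308 in control (SD, n = 3), with no overlap between the groups, for which an exact permutation test of 3 against 3 can give no p below 0.1. ND5, a complex I subunit and the member with the smallest p, stood at 510 ± 45.0 CPM against 903 ± 57.0 CPM. Transcripts of cytosolic ribosomal proteins and of nuclear-encoded oxidative phosphorylation subunits rose as lists, with positive values for 43 of 44 and 28 of 32 genes. Their medians were smaller, at 0.17 and 0.13, and neither list passed with an estimated correlation (adjusted p = 0.324 for both with an estimated correlation).

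**Figure D1:**
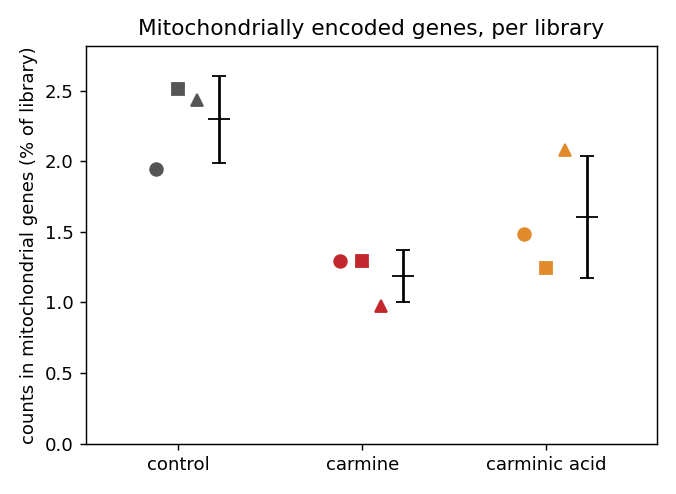
Counts on the mitochondrial chromosome as a percentage of all counts in each library (circles, replicate A; squares, B; triangles, C), with mean and SD per group (n = 3). The carmine libraries lie between 0.974% and 1.296%, below the control libraries at 1.945% to 2.515%, and the carminic acid libraries spread from 1.241% to 2.082%.

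No gene passed an adjusted p of 0.05 in edgeR for carmine against control. Groups did not overlap for 14.99% of genes, where 10% is only the average over random groupings. An unadjusted p under 0.05 was seen for 1760 genes, 862 higher and 898 lower, where chance gives 800.8. Regrouping the same 6 libraries gave up to 2153 such genes, for control A, control B and carmine C against the rest, so 1760 is not beyond what other groupings gave. DESeq2 called 81 genes, 17 of them higher, and limma-voom 51, 12 of them higher. Within edgeR, 122 genes passed with the trends removed (41 higher), 19 with no filter, 12 with only the 6 libraries compared, and 7 with RLE factors or library size alone. Among genes with an average log2 CPM of at least 0, the smallest p-values of higher genes belonged to NDUFB5 (Gene ID 4711), a subunit of respiratory complex I, CNIH1 (10175), a cargo receptor for export from the endoplasmic reticulum, and CYP1A1 (1543), the classical target of the aryl hydrocarbon receptor. NDUFB5, at positions 179604794 to 179627647 of chromosome 3, stood at 188 ± 18.9 CPM with carmine and 132 ± 5.89 in control (log2 fold change 0.51, SE 0.0799, edgeR adjusted p = 0.0536). CYP1A1, at positions 74719542 to 74725528 of chromosome 15, stood at 8.20 ± 0.979 CPM against 5.47 ± 0.238 (0.58, SE 0.114, adjusted p = 0.116). CNIH1 stood at 88.6 ± 1.10 against 68.9 ± 3.43 (0.36, SE 0.0712, adjusted p = 0.116). With the trends removed CNIH1 (edgeR adjusted p = 0.0117) and CYP1A1 (0.021) were among the 122 genes that passed, and NDUFB5 was not. Among lower genes within the same limit these were MST1P2 (11209; -0.64), a pseudogene of MST1 whose reads cannot be separated from those of its relatives here, the imprinted gene NNAT (4826; -1.16) and the glucosidase gene PGGHG (80162; -0.63), each with an adjusted p of 0.0536. The count of called genes was 36 without carmine library C, 11 without carmine library A and 5 without control library C.

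**Figure D2:**
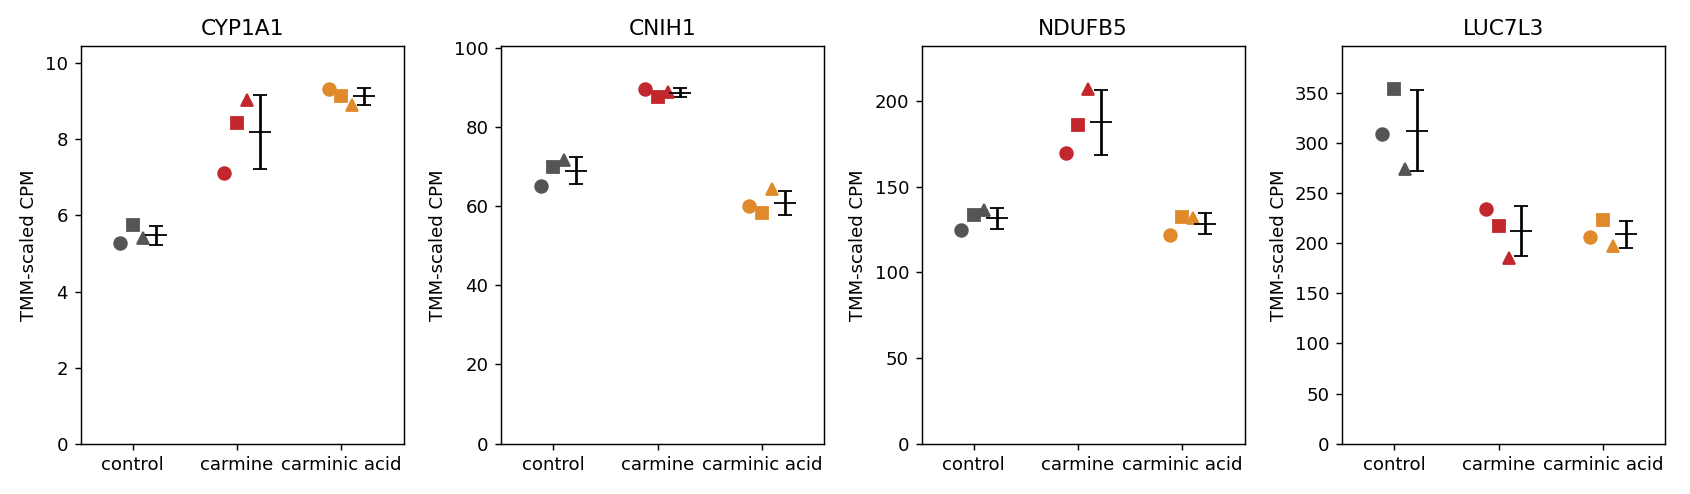
TMM-scaled CPM of CYP1A1, CNIH1, NDUFB5 and LUC7L3 in each library (circles, replicate A; squares, B; triangles, C), with mean and SD per group (n = 3). CYP1A1 was 8.20 CPM with carmine and 9.13 CPM with carminic acid against 5.47 CPM in control, while CNIH1 and NDUFB5 were highest with carmine and LUC7L3 was lowest in the treated groups.

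With carmine, 13 of 36 lists passed the camera threshold, 9 higher and 4 lower, none of them with an estimated correlation and 2 of them (metallothioneins and immediate early genes) with fry. The camera call of the metallothionein list ended without any 1 of the 6 libraries (camera adjusted p = 0.0578 to 0.291). The ribosomal list had an adjusted p of 2.32e-12 and the nuclear oxidative phosphorylation list one of 3.71e-07 (again adjusted p = 0.324 with an estimated correlation). Adjusted over the list alone, RPLP2 passed in the first (727 ± 73.9 CPM against 560 ± 19.1) and NDUFB5 and NDUFB10 in the second, against 0 of these over all genes tested. Adjusted over the list alone, 13 of the 15 mitochondrially encoded genes also passed. Hepatocyte-type genes, several of which Caco-2 cells express strongly, were positive in 18 of 20 (median 0.16, camera adjusted p = 6.77e-04; adjusted p = 0.324 with an estimated correlation). Among them were the serum protein genes TTR (109 ± 8.48 against 88.5 ± 2.29 CPM) and SERPINA1 (927 ± 31.7 against 807 ± 33.0 CPM). TF, the transferrin gene, stood at 0.568 ± 0.106 against 1.09 ± 0.0681 CPM. SERPINA1, NDUFB10 and MYC were chosen after their values were seen. Immediate early genes fell as a list, with 13 of 19 negative (median -0.12, adjusted p = 0.0135; adjusted p = 0.268 with an estimated correlation). The transcription factor gene EGR1 stood at 14.47 ± 1.496 against 18.6 ± 0.897 CPM and MYC at 54.3 ± 3.01 against 65.2 ± 2.32 CPM, and 3 members passed over the list alone.

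The other 8 called lists covered metabolism, metals and defence. Lysosome and autophagy genes were positive in 22 of 27 (median 0.07, adjusted p = 0.0136; adjusted p = 0.324 with an estimated correlation), with NPC2, a lysosomal cholesterol carrier, at 383 ± 25.8 against 326 ± 13.2 CPM. Glycolysis and gluconeogenesis genes were positive in 17 of 22 (0.10, adjusted p = 0.0192; adjusted p = 0.482 with an estimated correlation). Nutrient transporters were positive in 16 of 20 (0.11, adjusted p = 0.0306; adjusted p = 0.362 with an estimated correlation). The hypoxia list was positive in 18 of 24 (0.08, adjusted p = 0.0285; adjusted p = 0.434 with an estimated correlation), with BNIP3, a mitophagy receptor gene, at 421.8 ± 15.03 against 350.2 ± 13.97 CPM. NRF2 targets were positive in 17 of 26 (0.11, adjusted p = 0.0242; adjusted p = 0.324 with an estimated correlation) and the metallothionein and zinc list in 7 of 9 (0.19, adjusted p = 0.0467; adjusted p = 0.324 with an estimated correlation). Fatty acid synthesis genes were negative in 12 of 14 (-0.10, adjusted p = 0.0242; adjusted p = 0.362 with an estimated correlation), and NF-kB targets and cytokines in 17 of 22 (-0.14, adjusted p = 0.0288; adjusted p = 0.324 with an estimated correlation). Log2 fold changes for carmine followed transcript length (Spearman -0.43) and GC content (0.22) across 11104 genes. With these trends removed, a step added after the data were seen, the calls of glycolysis (0.102), NRF2 targets (0.0562), fatty acid synthesis (0.0804) and metallothioneins (0.0667) ended, with medians of 0.06, 0.06, -0.09 and 0.13. The cell cycle list gained a call (-0.04, adjusted p = 0.0224), while before removal it had an adjusted p = 0.748 with an estimated correlation. Among calls kept, medians were then 0.095 for hepatocyte-type genes, 0.04 for lysosome and autophagy genes (camera adjusted p = 0.0499) and 0.09 for nutrient transporters. They were -0.17 for immediate early genes, -0.16 for NF-kB targets and 0.09 for hypoxia. Leaving out 1 library ended the calls of 9 of the 13 lists, all but the mitochondrial, ribosomal, oxidative phosphorylation and hepatocyte-type lists.

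The other lists did not pass with carmine. Values of the median log2 fold change and adjusted p were -0.05 and 0.0688 for WNT targets and stem cells, 0.12 and 0.0688 for bile acid and FXR genes, 0.07 and 0.0688 for apoptosis, 0.06 and 0.0688 for PPAR targets, and 0.06 and 0.0704 for lipid transport. They were 0.05 and 0.131 for the brush border, 0.06 and 0.131 for ATF4 targets, and 0.04 and 0.160 for endocytosis. Further values were -0.02 and 0.169 for the cell cycle, 0.05 and 0.251 for p53 targets, 0.02 and 0.259 for the unfolded protein response, and -0.08 and 0.313 for epithelial-mesenchymal and matrix genes. Heat shock genes had 0.01 and 0.356, stromal, endothelial and immune markers -0.07 and 0.356, enteroendocrine and Paneth markers -0.20 and 0.397, and iron handling 0.05 and 0.423. Histones had 0.06 and 0.5003, cholesterol biosynthesis 0.02 and 0.617, goblet and secretory markers 0.06 and 0.725, and junctions 0.03 and 0.736. The aryl hydrocarbon receptor list had -0.06 and 0.848, with CYP1A1 as 1 of only 3 positive members of 10, the interferon response 0.01 and 0.848, and xenobiotic metabolism -0.03 and 0.880. Kidney and lung epithelium had 2 tested members, too few for a test. Mean and median differed in sign for lipid transport, junctions, iron handling, goblet markers and the interferon list, and the test took the sign of the median in all of these except the last.

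Among the genes fixed in advance for metal and stress responses, only CYP1A1 passed with carmine when adjusted over its list alone. HMOX1, an oxidant-induced heme oxygenase gene, stood at 75.0 ± 8.29 against 64.2 ± 1.05 CPM (log2 fold change 0.22, edgeR adjusted p = 0.399), and the p53 target CDKN1A at 122 ± 17.8 against 99.3 ± 3.52 CPM (0.29, adjusted p = 0.358). With the trends removed these were 0.13 (adjusted p = 0.232) and 0.21 (adjusted p = 0.0361). The metallothionein genes MT1X and MT2A were near the limit of detection, at 0.668 ± 0.193 and 0.611 ± 0.196 CPM against 0.478 ± 0.0567 and 0.448 ± 0.0720 CPM (log2 fold changes 0.48, 95% interval -0.17 to 1.14, and 0.45). Values were 0.05 for the zinc exporter gene SLC30A1, -0.02 for the transferrin receptor gene TFRC, 0.06 for the iron importer gene SLC11A2, 0.11 for NQO1 and 0.11 for CA9. The brush border genes SI, ALPI and VIL1 had values of -0.11, 0.08 and 0.01, and the efflux pump genes ABCB1 and ABCG2 values of -0.10 and -0.15. CXCL8, DDIT3 and HMGCS1 had values of -0.05, 0.03 and -0.03. With the trends removed VIL1 moved to 0.09 and CA9 to -0.002. Adjusted p-values of this set, CYP1A1 aside, ran from 0.358 to 0.973.

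The carminic acid comparison asked the same of the dye without aluminium, at 20 µM. CYP1A1 was again among the genes with the smallest p, at 9.13 ± 0.216 CPM against 5.47 ± 0.238 in control (log2 fold change 0.74, SE 0.114, 95% interval 0.49 to 0.98, edgeR adjusted p = 0.129), and passed when adjusted over the list alone (1.25e-04). Genes of the enterocyte brush border rose as a list with carminic acid, with 24 of 28 positive (median 0.14, camera adjusted p = 1.08e-05; adjusted p = 0.246 with an estimated correlation). Its member with the smallest p was LCT, the lactase gene, at 24.0 ± 0.280 against 18.7 ± 2.39 CPM. With the trends removed the median of this list was smaller, at 0.08 (camera adjusted p = 1.59e-05). Lysosome and autophagy genes rose as a list, with 23 of 27 positive (0.10, adjusted p = 1.22e-05; adjusted p = 0.246 with an estimated correlation), with the protease gene CTSD at 1390 ± 128 against 1155 ± 68.4 CPM (0.27, and 0.15 with the trends removed). The mitochondrially encoded genes fell as a list here too, all 15 with negative values and a median of -0.48 (adjusted p = 1.24e-11; adjusted p = 0.372 with an estimated correlation). With 1 library left out the median ran from -0.78 to -0.35. Their chromosome took 1.60% ± 0.433 of counts, and carminic acid library C, at 2.082% (95% interval 2.078 to 2.086), lay above control library A at 1.945% (1.941 to 1.949).

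No gene passed an adjusted p of 0.05 in edgeR for carminic acid against control. An unadjusted p under 0.05 was seen for 1030 genes, 403 higher and 627 lower, and other groupings of these 6 libraries gave at most 737. Groups without overlap were seen for 20.8% of genes, where 10% is the average over random groupings. A trend common to many genes can raise this share. Log2 fold changes followed GC content (Spearman 0.67), and per library the coefficients were 0.15, 0.74 and 0.31 with carminic acid and 0.07, -0.35 and -0.70 in control. Shares under other groupings were not counted. DESeq2 called 6 genes, 1 of them higher, and limma-voom 82, 25 of them higher. Within edgeR, 49 genes passed with only the 6 libraries compared (13 higher), 3 with the trends removed and 2 with no filter. Besides CYP1A1, the smallest p-values of higher genes with an average log2 CPM of at least 0 belonged to the cadherin gene CDH4 (1002; 28.8 ± 1.72 against 20.4 ± 3.18 CPM, 0.50) and the potassium-chloride cotransporter gene SLC12A7 (10723; 40.5 ± 6.15 against 29.9 ± 0.520 CPM, 0.44). Among lower genes within this limit they belonged to LUC7L3 (51747), a splicing factor gene, at 209 ± 13.2 against 312 ± 40.3 CPM (-0.58, SE 0.101, adjusted p = 0.229). The same held for PNISR (25957), which encodes an arginine- and serine-rich protein, at 59.5 ± 2.62 against 84.3 ± 7.71 CPM (-0.50, adjusted p = 0.455), and ARGLU1 (55082), another splicing-related gene, at 46.8 ± 2.82 against 61.0 ± 4.40 CPM (-0.38, adjusted p = 0.545). With the trends removed these were -0.46, -0.36 and -0.28, and SLC12A7 was 0.33.

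With carminic acid, 10 of 36 lists passed, 8 higher and 2 lower, none of them with an estimated correlation or with fry. Glycolysis genes were positive in 20 of 22 (0.10, adjusted p = 3.22e-04; adjusted p = 0.542 with an estimated correlation). Nutrient transporters were positive in 17 of 20 (0.10, adjusted p = 6.66e-04; adjusted p = 0.372 with an estimated correlation), with SCARB1, a lipoprotein receptor gene, at 353 ± 18.6 against 308 ± 15.1 CPM. Hepatocyte-type genes were positive in 15 of 20 (0.10, adjusted p = 0.00349; adjusted p = 0.372 with an estimated correlation), with the fibrinogen gene FGA at 160 ± 3.79 against 137 ± 1.96 CPM. Ribosomal protein genes were positive in 35 of 44 (0.07, adjusted p = 0.00607; adjusted p = 0.786 with an estimated correlation). Endocytosis genes were positive in 24 of 30 (0.08, adjusted p = 0.00807; adjusted p = 0.246 with an estimated correlation) and junction genes in 16 of 20 (0.08, adjusted p = 0.0154; adjusted p = 0.246 with an estimated correlation). Cell cycle genes were negative in 23 of 30 (-0.08, adjusted p = 0.0338; adjusted p = 0.784 with an estimated correlation), with PCNA at 44.3 ± 2.05 against 52.8 ± 7.21 CPM. Over the list alone, 1 member of all lists passed, CYP1A1, and 0 over all genes tested. Adjusted p-values of the other 26 lists ran from 0.192 for PPAR targets to 0.894 for goblet and secretory markers. Mean and median differed in sign for lipid transport, the aryl hydrocarbon receptor list and the interferon list, and the test followed the mean for the receptor list only.

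Among the genes fixed in advance, HMOX1 stood at 75.9 ± 5.35 against 64.2 ± 1.05 CPM with carminic acid (0.24, edgeR adjusted p = 0.717) and CDKN1A at 115 ± 3.48 against 99.3 ± 3.52 CPM (0.21, adjusted p = 0.717). CXCL8, the interleukin 8 gene, was low in both groups, at 0.934 ± 0.435 against 1.57 ± 0.455 CPM (-0.74). With the trends removed HMOX1 had 0.15 and CDKN1A 0.12. Values were 0.19 for MT1X, 0.08 for MT2A, 0.10 for SLC30A1, -0.03 for NQO1, -0.06 for TFRC, 0.02 for SLC11A2 and 0.11 for CA9. SI, ALPI and VIL1 had values of 0.01, 0.16 and 0.12, ABCB1 and ABCG2 of -0.06 and -0.13, and DDIT3 and HMGCS1 of 0.03 and -0.18. Several moved with the trends removed, to 0.23 for SLC30A1, 0.02 for TFRC, 0.13 for SI, 0.05 for ALPI, -0.08 for HMGCS1 and 0.01 for CA9. Log2 fold changes for carminic acid followed GC content with a Spearman coefficient of 0.67 across genes. With the trends removed the 10 list calls were kept, the brush border with a smaller median of 0.08, and 9 were gained. Those gained were higher for PPAR targets (0.0117), nuclear oxidative phosphorylation (0.0217), the unfolded protein response (0.0227), hypoxia (0.0295), iron handling (0.0333) and lipid transport (0.0471). They were lower for immediate early genes (0.00607), cholesterol biosynthesis (0.0227) and WNT targets (0.0379). None of these 9 passed before removal with an estimated correlation (adjusted p = 0.542 to 0.853 with an estimated correlation). Leaving out 1 library ended the calls of 3 lists: junctions without carminic acid library C (0.0730), the cell cycle without control library B or C or carminic acid library B or C (0.315, 0.432, 0.214 and 0.293), and ribosomal proteins without control library A or carminic acid library B or C (0.0946, 0.214 and 0.117), each for carminic acid against control.

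**Figure D3:**
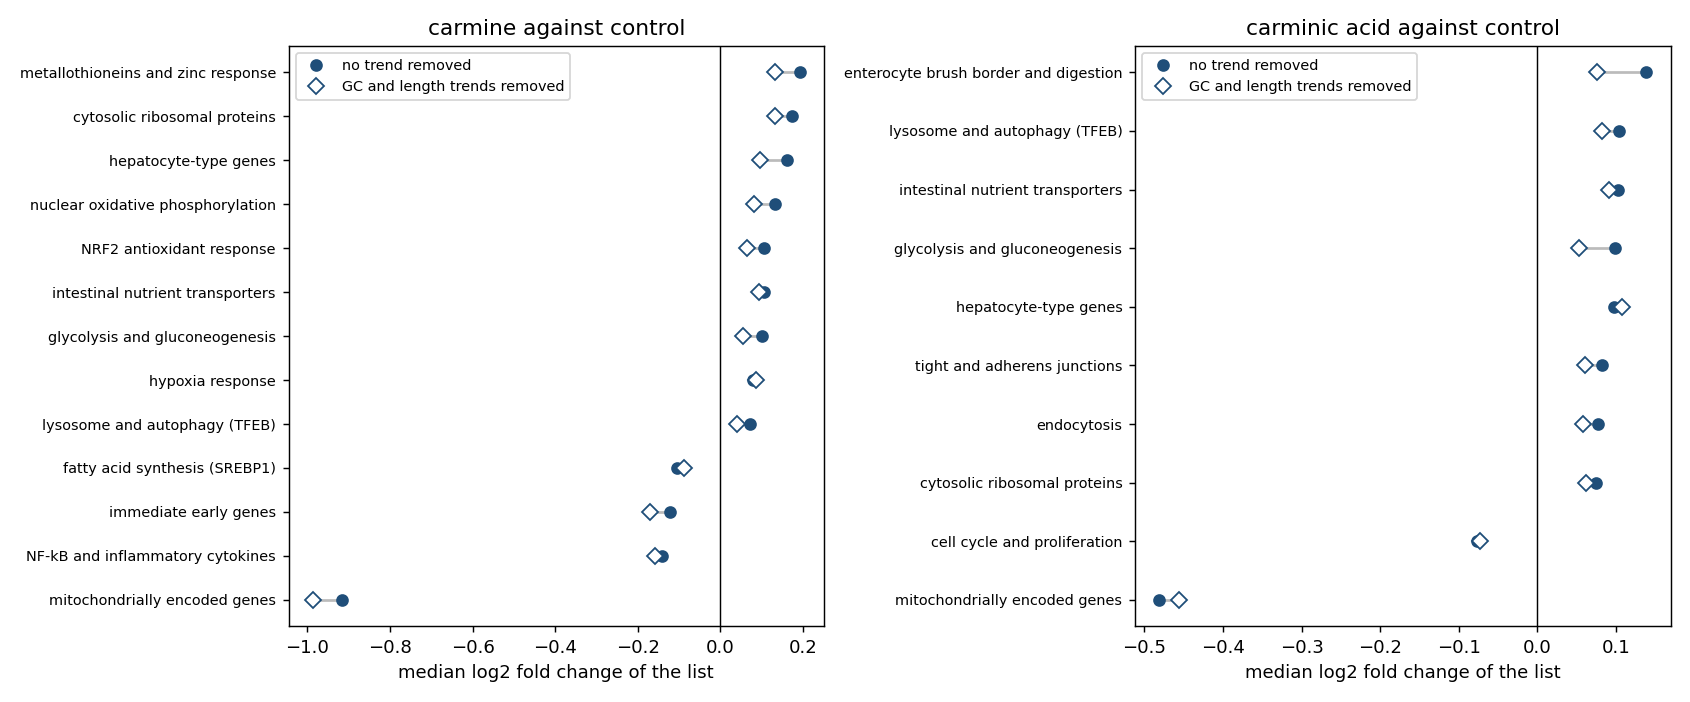
Median log2 fold change of each list that passed the camera threshold against control, for carmine (left) and carminic acid (right), without correction (filled circles) and with the trends of each library with GC content and transcript length removed (open diamonds). The mitochondrially encoded genes lie at -0.92 and -0.99 with carmine and at -0.48 and -0.46 with carminic acid, and the other medians lie between -0.17 and 0.19.

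The direct comparison of the colorants tested where their responses differed, at stated concentrations of 10 µM and 20 µM. Whether these match in dye units is not given, since a complex can hold more than 1 carminic acid unit. CNIH1, at positions 54423561 to 54441374 of chromosome 14, was the 1 gene past the threshold in edgeR: it stood at 88.6 ± 1.10 CPM with carmine and 60.8 ± 3.09 CPM with carminic acid (n = 3), with 68.9 ± 3.43 CPM in control between them (log2 difference 0.54, SE 0.0714, 95% interval 0.39 to 0.70, adjusted p = 0.0312). Mitochondrially encoded genes were lower with carmine than with carminic acid, all 15 with negative values (median -0.42, camera adjusted p = 9.95e-08; adjusted p = 0.740 with an estimated correlation). With 1 library left out this median ran from -0.57 to -0.18. Ribosomal protein genes were higher with carmine in 40 of 44 (0.11, adjusted p = 1.80e-05; adjusted p = 0.778 with an estimated correlation), and nuclear oxidative phosphorylation genes in 26 of 32 (0.13, adjusted p = 4.51e-05; adjusted p = 0.778 with an estimated correlation). Brush border genes were lower with carmine in 19 of 28 (-0.07, adjusted p = 0.0420; adjusted p = 0.740 with an estimated correlation), with LCT at 18.4 ± 1.04 against 24.0 ± 0.280 CPM. With 1 library left out the medians ran from 0.05 to 0.18 for ribosomal proteins and from 0.08 to 0.17 for oxidative phosphorylation, and with the trends removed both were 0.05 (0.0487 and 0.0547). The brush border call ended with the trends removed (-0.04, adjusted p = 0.139) and without any of 4 of the 6 libraries. Adjusted over the list alone, 4 genes passed, against 0 of these over all genes tested: LCT, MSMO1 of cholesterol synthesis, the glucuronidation gene UGT2B17 and NDUFB5 (188 ± 18.9 against 128 ± 5.95 CPM, 0.55). With the trends removed MSMO1 went from 0.38 to 0.22 and UGT2B17 from 0.38 to 0.21.

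Between the colorants, 13.1% of genes had groups without overlap, where 10% is only the average over random groupings. At an unadjusted p under 0.05, 1426 genes were counted, 905 higher with carmine and 521 lower. Another grouping of these 6 libraries gave 3447 such genes. DESeq2 called 77 and limma-voom 82. Among lower genes with an average log2 CPM of at least 0, the smallest p-values belonged to BTBD7 (55727; 0.828 ± 0.259 against 2.65 ± 0.915 CPM, -1.67, edgeR adjusted p = 0.123), the pseudogene MST1P2 (-0.46, adjusted p = 0.209) and ITPR3 (3710), a calcium release channel gene, at 329 ± 9.85 against 401 ± 18.3 CPM (-0.28, adjusted p = 0.290, and -0.12 with the trends removed). For CYP1A1 the difference was -0.15 (95% interval -0.39 to 0.08), for HMOX1 -0.02 (-0.20 to 0.17), for CDKN1A 0.08 (-0.11 to 0.28), for TFRC 0.04 (-0.12 to 0.20) and for SLC30A1 -0.06 (-0.22 to 0.11). For MT1X the interval was wide, from -0.36 to 0.94. The other 32 lists had adjusted p-values from 0.0557, for epithelial-mesenchymal and matrix genes, to 0.986, and mean and median differed in sign for iron handling, the aryl hydrocarbon receptor, xenobiotic, interferon and enteroendocrine lists. The CNIH1 call ended without carmine library B (adjusted p = 0.209), carminic acid library A (0.490) or carminic acid library B (0.150). It also ended with the replicate letter as a block (0.0928), with non-robust estimation (0.0506) and in a fit of only the 6 libraries compared (0.101). Without carmine library C, 685 genes passed, 507 of them higher with carmine, and no list did.

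The responses to the colorants were also set side by side, which asks how far carmine and carminic acid shared a response. Across genes, the log2 fold changes against the shared control correlated with r = 0.54, where simulated unchanged groups with shared controls gave 0.50 on average and 0.53 at most, and the covariance exceeded the simulated mean of 0.0276 by 0.0149. The simulations drew genes independently, while real libraries carried GC trends (Spearman -0.70 to 0.74), so their range can be too narrow to judge r or the covariance. With 1 library left out r ran from 0.376, without carmine library C, to 0.591, without control library C. The r of unchanged groups itself shifts with the number of control and treated libraries, and the simulations kept every library. This range therefore cannot be set against the simulated values. At an unadjusted p under 0.05, 333 genes had the same sign with both colorants, 106 higher and 227 lower, where the simulations gave 153 on average and 178 at most. The simulations had 768 genes on average at this p for carmine, against the real 1760, so the excess does not by itself show a shared response. Adjusted p-values gave 0 genes shared in edgeR, 5 with DESeq2 and 17 with limma-voom. CYP1A1 was called by DESeq2 and limma-voom with carmine and with carminic acid. The control libraries cannot be divided so that each colorant has its own controls with replicates.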

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

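The tests of explanations in this part were chosen after the results were seen, and the rule that compares each value with its spread was changed after its first outcome was seen. The contrast of carmine with carminic acid tested the differences directly, at 10 µM and 20 µM. CNIH1 was 0.54 higher with carmine, and among lists the differences were -0.42 for mitochondrially encoded genes, 0.11 for ribosomal proteins, 0.13 for nuclear oxidative phosphorylation and -0.07 (-0.0706) for the brush border. None of these 4 lists passed with an estimated correlation (adjusted p = 0.740 to 0.778 with an estimated correlation), and with trends removed the ribosomal and oxidative phosphorylation medians were 0.0487 and 0.0547. Stated concentration and aluminium differed together, so neither can be named as the cause.

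Mitochondrially encoded transcripts were lower as a list with both colorants at the preset correlation (adjusted p = 0.268 and 0.372 with an estimated correlation), and carminic acid C (2.082%) overlapped control A (1.945%) in share. A trend with GC content and transcript length could lower them, but the median with carmine was -0.99 (-0.9868) once these trends were removed. Reads lost to nuclear copies would raise the copies, and the 10 MTRNR2L copies of the rRNA gene RNR2 had a log2 ratio with carmine of -0.77 (-0.7707). They held only 94 to 232 counts per library and speak for no other mitochondrial gene. Reads dropped as mapping to several places would raise no copy, so reads assigned elsewhere or dropped stay open. Over the 84 ways to choose 3 control libraries, 2 gave a difference in mitochondrial share as large as the real -0.903, with 0.971 the highest other (exact permutation p = 0.0238). The share was tested because the list stood out in the same libraries, so this does not exclude a grouping by luck. An effect of the colorants on mitochondrial RNA and a difference in RNA extraction were not tested and stay open.

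Ribosomal protein and nuclear oxidative phosphorylation transcripts were higher with carmine. A technical trend could explain part of the first: its median was 0.13 (0.1323) with the trends removed and 0.17 before, with an SD of 0.0418 over medians with 1 library left out. Carmine library C might carry part of the second, whose median without that library was 0.07 (0.06967) against 0.13 with it. The second was 0.08 with the trends removed and the first 0.12 without carmine C, and both lists still passed in each case at the preset correlation, though neither passed with an estimated correlation (adjusted p = 0.324 for both with an estimated correlation). Both explanations and an effect of carmine cannot be told apart here.

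The 10 splits of 6 libraries are too few for a share under 0.05. For carmine against control, 10 splits had as many called genes as the real 0 (highest other 1), and 1 had as many lists as the real 13 (highest other 8). For carminic acid against control these were 10 for genes (0, highest other 1) and 3 for lists (10, highest other 13). For carmine against carminic acid they were 3 for genes (1, highest other 1) and 6 for lists (4, highest other 8).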

How the results depend on the processing

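Removal of GC and length trends, pooling of the colorants and overlap at an unadjusted p were chosen after results were seen. For carmine against control, where 0 genes passed, 7 passed with RLE factors, 7 with library size only, 19 with no filter, 81 with DESeq2, 51 with limma-voom, 122 with trends removed and 12 with only the 6 libraries. Leaving out 1 library gave 1 to 36: 1 without control A, control B or carmine B, 5 without control C, 11 without carmine A and 36 without carmine C. For carminic acid against control (0), no filter gave 2, DESeq2 6, limma-voom 82, trends removed 3 and only the 6 libraries 49. With 1 library left out it was 0 to 1, with 1 without control B, carminic acid B or carminic acid C. The cause of these moves was not tested.

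For carmine against carminic acid (1), RLE factors and library size only gave 2 each, no filter 9, DESeq2 77, limma-voom 82 and trends removed 7. Non-robust estimation gave 0 (CNIH1 adjusted p = 0.0506), as did an adjusted p under 0.01 and an absolute log2 fold change of at least 1. With only the 6 libraries 1 gene passed, which was not CNIH1 (0.101). Leaving out 1 library gave 0 to 685: 0 without carmine B or carminic acid A, 1 (not CNIH1) without carminic acid B, 3 without carmine A or carminic acid C, and 685 without carmine C.

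The replicate letter as a block, a pairing the labels do not state, gave 0 genes in these 3 comparisons, also with library size only, and 3 with the colorants pooled, none higher. It gave 13, 10 and 5 lists for carmine against control, carminic acid against control and carmine against carminic acid. The correlation of the responses was 0.536 with the block.

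That correlation (0.54) ran from 0.376 to 0.591 with 1 library left out: 0.467 without carmine B, 0.376 without carmine C and 0.452 without carminic acid C. The r of unchanged groups also shifts when a library is left out and was not simulated for these fits, so the moves cannot be judged. Shared calls (0) were 1 with no filter, 5 with DESeq2, 17 with limma-voom, 3 with trends removed and 333 at an unadjusted p. Without 1 library they were 0 to 5, with 1 without control B, carmine A or carmine B and 5 without carmine C. Controls of its own for each colorant could not be run.

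With an estimated correlation 0 lists passed in each comparison, and with fry 2, 0 and 0. For carmine against control (13), library size only gave 11, CPM above 1 gave 15 and trends removed 10. With each library left out in turn it was 6 to 13, with 8 without carmine A and 6 without carmine C. For carminic acid against control (10), trends removed gave 19 and leaving out 1 library 7 to 11. For carmine against carminic acid (4), trends removed gave 3 and leaving out 1 library 0 to 6, with 0 without carmine C. Each remaining entry took 1 named gene, 1 called list or the pooled count in 1 alternative setting. Of these entries, which are not separate results, 2879 stayed the same, 110 became weaker, 116 stronger and 90 moved. No named gene but CNIH1, between the colorants, was called in the first place. For an uncalled gene, same means still uncalled and within 1 SE of the reported fold change.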

Other observations

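The tests in this part, and the pooling of both colorants against control, were chosen after the results were seen. With the 6 treated libraries pooled, 3 genes passed in edgeR: CYP1A1 (0.66, adjusted p = 0.0478), LUC7L3 (-0.57, adjusted p = 0.0213) and TBC1D3D (-3.23, adjusted p = 0.00173), whose reads cannot be separated from close copies. CYP1A1, the only higher gene, was not called with the block, with CPM above 1 or without control A, B or C, carmine B or carminic acid A, and LUC7L3 was not called with trends removed (-0.48, 0.0715), while CYP1A1 then had an adjusted p of 0.00798. Only 1 of the 3 was kept without control A, control B or carminic acid A. The count was 1 to 13 with 1 library left out, 30 with trends removed, 39 with DESeq2 and 109 with limma-voom. Of 84 splits, 3 called at least the real 3 genes, and the highest other called 1445. That split set carmine C, carminic acid B and carminic acid C against the rest, which points to a structure of the samples. These are the libraries with the highest Spearman coefficients with GC content (0.609, 0.744 and 0.312), and the cause was not tested.

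Removal of GC and length trends called 122 genes with carmine, 81 of them lower, among them the splicing-related genes CLK1 and CCNL2 (both chosen after their values were seen). The 69 of these lower genes with transcript data had 4.48 annotated transcripts with a retained intron on average, above all matched sets (percentile 100, mean 1.85, or 2.67 when also matched on transcript number). A smaller share of nuclear RNA in the treated libraries could lower such genes. The annotation counts no intron reads in these libraries, and sets were not matched on GC content, length or intron number, so it cannot show such a share. Across 10787 protein-coding genes with log2 CPM above 2 the trend was weak after removal, with a Spearman coefficient of -0.111 with carmine and -0.0439 with carminic acid. Before removal the coefficients were -0.127 with carmine and 0.028 with carminic acid, so the negative sign with carminic acid appeared only after removal. With trends removed, the nuclear RNAs MALAT1, NEAT1 and KCNQ1OT1 (chosen after values were seen) had -0.36, -0.41 and -0.15 with carmine and -0.63, -0.55 and -0.30 with carminic acid, none with an adjusted p under 0.05 in edgeR. These RNAs had lower values with carminic acid, where the retained-intron trend was weaker after removal and had the other sign before it. Their mean over both colorants was -0.39 (4 of 84 splits as large, exact permutation p = 0.0476), a p that cannot count as support, since these RNAs were chosen after their values were seen. Of the 81 lower genes, 80 had the same sign with carminic acid, as had 31 of the 41 higher genes. Carminic acid shares the controls, and no value for unchanged groups was computed for these sets, so this does not show a shared response. Only 2 lower genes were called with carminic acid. Genomic DNA in the control libraries might do the same, but the olfactory receptor share had a log2 ratio of -0.21 (-0.2144, SE 0.163), which leaves it open. A regulated change of these genes was not tested.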
